A study of Mus musculus with 12 samples.

How the data were processed

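Poly(A)-selected RNA was sequenced from mouse embryonic stem cells of the E14 line, in 3 genotypes (wild type, p53 knockout and Dux knockout), each given doxorubicin or its vehicle. By the labels, 12 libraries fall into 6 groups of 2. The series' design text calls the duplicates biological. Column headers give the knockout libraries a line number, so library 1 of a knockout group comes from the same line as library 1 of the other group of that knockout, and likewise library 2. Wild-type columns carry no replicate number, so they are called a and b here and were never paired.

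Gene counts were used as the authors deposited them, as whole numbers per Ensembl gene for each library. The authors deposited FPKM values for the same libraries, and the same table holds the authors' log2 fold changes with standard errors and the authors' adjusted p-values for their own comparisons. TopHat2, DESeq and DESeq2 are named, with build mm10, in the submitters' processing notes. Their versions, the read counter, the annotation and the strand setting were not given in the sources used here. Another 6 columns of that FPKM table, which hold group averages, were not used. Of 54532 gene identifiers in the deposited count table, 54409 were found in the GENCODE M21 annotation of GRCm38 (mm10), which gave gene names, positions and lengths.

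What the deposited values hold was checked on the values themselves. Over 7446 genes, the gene length implied by count and FPKM lay within 1% of a fixed multiple of the whole gene span in 98.2%, and of the exonic length in 0.7%. The counts therefore cover gene spans with their introns. Of 561 genes lying wholly in an intron of a gene on the opposite strand, 558 had no more counts than the outer gene in any library, and the same held for 363 of 363 genes in an intron of a gene on their own strand. Strand was thus not used in counting, and reads of overlapping or antisense genes cannot be told apart. Of counts of at least 500, 26.4% to 33.4% were odd in the 11 libraries used, so counts are not independent single reads. Intervals and floors cover counting error only and are too tight unless counts were halved.

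The count column labelled as Dux KO control library 2 holds, in 54532 of 54532 genes, the same value as the column of Dux KO doxorubicin library 1. Over 10563 genes with more than 200 counts, the SD of the log2 ratio of count to FPKM was 0.0018 with the FPKM of that drug-treated library and 0.834 with the FPKM of the column's own label. No other column exceeded 0.002 with its own FPKM. The column was left out of all tests, which leaves 11 libraries and a single Dux KO control library, assumed in every test to vary like the other groups. The FPKM column of the missing library is distinct, so its counts were recovered from it. Of 5796 low FPKM values, 99.98% lay within 0.15 of a whole read, giving 55645650 reads. In libraries with known counts the same procedure gave at least 96.6% of genes within 1 read or 1%, and at least 80.09% exact. Results with the recovered counts were added as an alternative after the data were seen.

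Total counts ran from 23270358 to 56795858 per library. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with the group (minimum count 10), a model with a mean per group over the 11 libraries, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 28643 genes kept. A gene was called at an adjusted p under 0.05. The model has 5 residual degrees of freedom. All groups share 1 estimate of the spread, because 2 libraries per group are too few for separate ones. Levels are CPM (counts scaled to TMM-corrected library size), given as mean ± SD of 2 libraries, with no SD for the single Dux KO control library. A fold against a group at 0 in all libraries was set against a floor of 3 counts per library and called a lower bound. Sizes of the largest interactions are given with groups below that floor set to it, which was decided after the data were seen. A ratio resting on 1 to 3 counts is given with its 95% counting interval. The comparisons were the response to doxorubicin in each genotype, the difference between each knockout's response and the wild-type response (the interaction), and each knockout against wild type under vehicle and under drug.

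Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. The 20 lists were p53 targets, 2-cell-stage (Dux-induced) genes, 2-cell-stage genes outside multigene families, naive pluripotency, primed pluripotency, trophectoderm, primitive endoderm, primitive streak and mesoderm, neuroectoderm, germline and meiosis, fibroblast, G2/M and mitosis, G1/S and DNA replication, DNA repair, interferon response, stress and immediate early, apoptosis, ribosome biogenesis, replication-dependent histones, and mitochondrially encoded transcripts. None of the 15 mitochondrial transcripts had counts enough to be tested (0 tested), so 19 lists were. Named genes follow a rule: Trp53 and Dux (Duxf3) first, then the 8 largest rises and 6 largest falls of the wild-type response, the 5 largest in each direction of every other comparison, and up to 4 members of each list by smallest p, or 8 for the p53 and 2-cell lists. Largest changes were taken among called genes with a mean of at least 1 CPM whose groups did not overlap, a condition dropped for interactions. Groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except where a choice is said to have been made later.

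Alternatives were edgeR with DESeq2's size factors (RLE), DESeq2 1.42.0, no filter on low counts, only the groups compared, a minimum log2 change of 1, limma on log2(FPKM + 1) with at least 1 FPKM in 2 libraries, on log2(FPKM + 0.1) and without that filter, the replicate number as a block within genotype, and each library left out in turn. The block was considered because the line numbers pair the knockout libraries: deviations from the group means correlated between same-numbered libraries at r = 0.46 in p53 KO and r = 0.20 in Dux KO over 26975 genes, which are not independent of each other. In comparisons between genotypes the block takes the difference between lines out of the spread, so it speaks for these lines alone. For lists, an estimated correlation and fry were alternatives. Added after the data were seen were the recovered counts, the block together with the recovered counts, the copied column kept under its label, and counts of calls without genes that overlap another gene.

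The scripts were tested on simulated data in which 100 genes were changed 2-fold and 100 changed 4-fold. Of 4-fold changes, 70% were called in a simulated wild-type response over 26832 genes, 66% in a p53 KO response over 26798, 53% in a Dux KO response over 26821, and 38% in a p53 KO interaction over 26762. Of 2-fold changes the shares were 12%, 20%, 5% and 0%, and between 2 and 7 unchanged genes were called.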

Results

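Doxorubicin poisons topoisomerase II and breaks DNA, and the breaks activate the transcription factor p53. The data measure the poly(A) RNA of mouse embryonic stem cells (E14, grown with LIF and the 2i kinase inhibitors) after 1 uM doxorubicin for 6 h followed by drug-free medium, or after DMSO vehicle. Wild-type cells, cells without p53 and cells without Dux, a transcription factor of the embryo's 2-cell stage, were compared, with 2 biological replicates per group by the design text. The time in drug-free medium was not given in the sources used. Both wild-type replicates carry the name of 1 line and the knockout replicates carry line numbers 1 and 2, so the knockout spread also holds the difference between lines. Counts of Dux KO control library 2 were left out because its column repeats that of Dux KO drug library 1 in all 54532 genes, so 11 libraries were tested. The lone Dux KO control was assumed to vary like the other groups. Levels below are mean CPM ± SD of 2 libraries, without SD for the lone Dux KO control. The first principal component held 55% of the variance. On it the drug-treated wild-type libraries lay at 238.6 and 252.5, the Dux KO ones at 56.3 and 69.1, the p53 KO ones at 12.9 and -15, and the controls between -123.5 and -85, with Dux KO control 2 included as its counts were recovered from FPKM. Genes with counts numbered 33629 and 34297 in drug-treated against 28488 and 28606 in control wild-type cells. Wild-type drug library b carried 6.13% of its counts in 3 ribosomal RNA loci, more than any other library. Strand was not used in counting, so counts of overlapping genes cannot be told apart.

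The targeted genes were looked at first in every sample. Trp53 (ENSMUSG00000059552, chr11:69580359-69591873, GRCm38/mm10) stood at 193 and 159 CPM in wild-type controls and 135 and 133 CPM after drug. In p53 KO cells it stood at 72.4 and 39.8 CPM in controls and 95.5 and 42.6 CPM after drug. Dux KO cells had 243 CPM in the control and 135 and 136 CPM after drug. The kind of edit is not given in the sources used, so the RNA that remained says little about the protein. The difference between p53 KO and wild-type controls was not called (log2 -1.65, edgeR adjusted p = 0.084). With a replicate block, which sets p53 KO cells at the level of line 1, Trp53 in p53KO baseline libraries had log2 -1.20 (edgeR adjusted p = 9.2e-05). DESeq2, without a block, gave adjusted p = 0.00043. Duxf3, the gene for Dux (chr10:58229979-58232675, in a tandem array of near-identical copies), had 2 and 0 counts in wild-type controls and 670 and 685 after drug. It had 0 and 14 counts in p53 KO controls, 114 and 20 in p53 KO drug libraries, and 0 in every Dux KO library.

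The first question was what doxorubicin does to wild-type cells. Genes that p53 switches on rose. Mdm2, which encodes the ligase that degrades p53, went from 155 ± 8.98 to 949 ± 1.80 CPM (chr10:117688875-117710758; log2 2.62, SE 0.15, edgeR adjusted p = 8.6e-06). Ppm1d, a phosphatase that ends the damage signal, rose from 27.5 ± 1.12 to 84.1 ± 4.07 CPM (log2 1.61). Abhd4 rose from 39.5 ± 3.63 to 247 ± 17.7 CPM (log2 2.64). Of 40 p53 targets, 28 rose, 1 fell and 11 were not called. Adjusted over the list alone the counts were again 28 and 1 (median log2 1.27, camera adjusted p = 9.3e-06, adjusted p = 0.59 with an estimated correlation).

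Duxf3 rose 581-fold in wild-type cells (nominal 95% counting interval 161 to 4800, log2 9.05, edgeR adjusted p = 0.0012). The genes that Dux switches on at the 2-cell stage rose with it. Zfp352 went from 0.188 ± 0.157 to 75.7 ± 14.6 CPM (chr4:90218820-90225702; log2 8.61, SE 0.57, adjusted p = 1.8e-05). Zscan4a rose from 0.400 ± 0.0161 to 292 ± 24.0 CPM (chr7:10794242-10799057; log2 9.50) and Zscan4c from 1.33 ± 0.234 to 496 ± 66.4 CPM (log2 8.54). Usp17le rose from 0.501 ± 0.391 to 269 ± 39.5 CPM (log2 9.07). All 47 tested members of the 2-cell list rose, by a median log2 of 8.14, or 7.85 with zero groups set to the floor. The list was called (47 up and 0 down adjusted over the list alone, camera adjusted p = 2.8e-27, adjusted p = 0.37 with an estimated correlation). Zscan4, Usp17 and Dux genes lie in families of near-identical copies, so reads may be shared among copies. The 9 members outside such families also all rose, 9 up and 0 down adjusted over the list alone (median log2 7.96, camera adjusted p = 2.2e-07, adjusted p = 0.37 with an estimated correlation). Of these 9, Nat8f2, Arg2 and Sp110 still share 17.9%, 21.2% and 42.3% of their 50-base words with other genes.

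**Figure D1:**
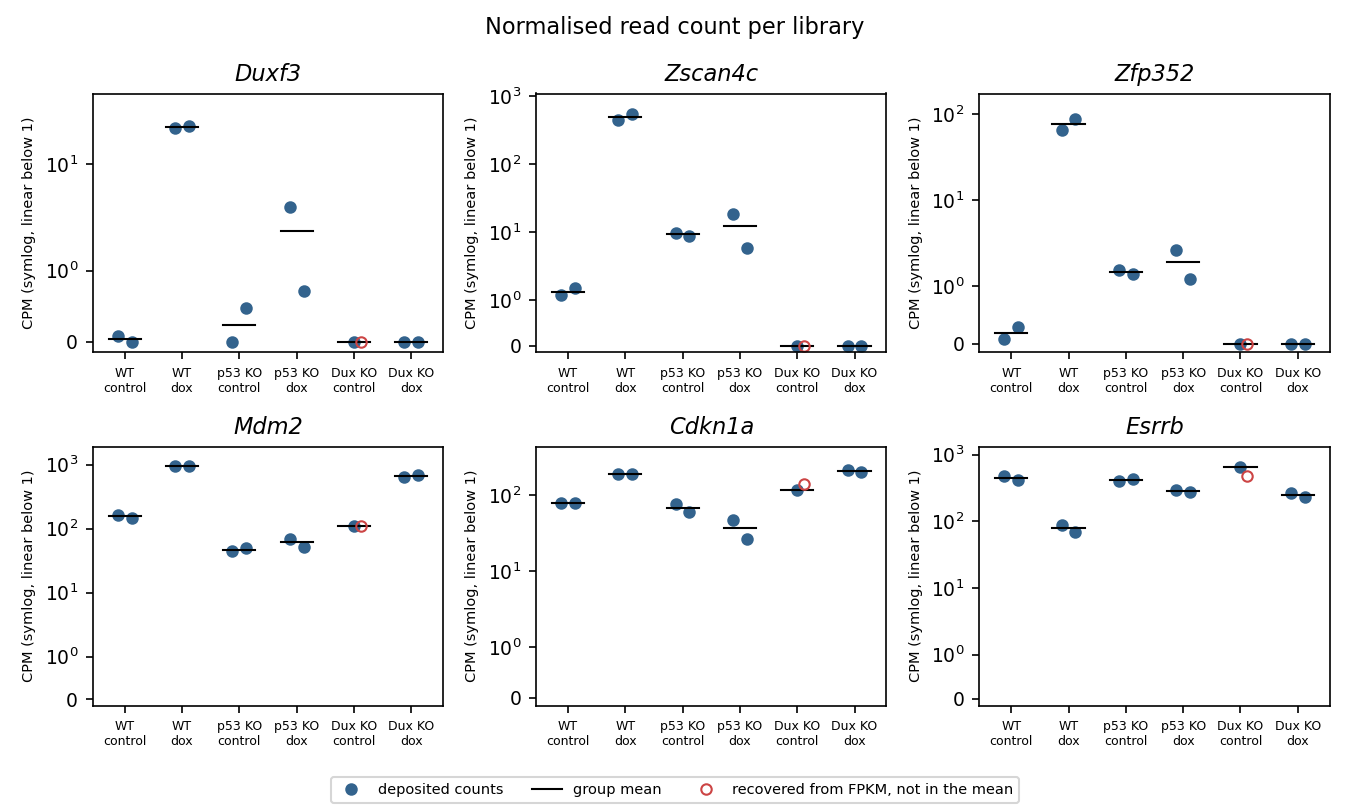
CPM of Duxf3, Zscan4c, Zfp352, Mdm2, Cdkn1a and Esrrb in each library on a scale linear below 1 CPM. Filled dots are deposited counts, lines are group means, and the open red dot is Dux KO control 2 as recovered from its FPKM, outside the mean.

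The 8 largest rises of the wild-type response by the fitted log2, whose size from 0 counts the fit's offset sets, started from 0 counts in both controls. Gm7957, a processed pseudogene (ENSMUSG00000108831, chr7:83411977-83414578), reached 172 ± 23.8 CPM (at least 1500-fold higher, edgeR adjusted p = 0.00017). Gm11544 (chr11:94845358-94846092) reached 70.8 ± 2.01 CPM (at least 619-fold) and Gm9343 46 ± 0.658 CPM (at least 402-fold). BC080695 reached 42.2 ± 3.09 CPM (at least 369-fold) and Gm33248 41.2 ± 9.26 CPM (at least 361-fold). Gm47631 reached 41.0 ± 1.21 CPM (at least 359-fold), the X-linked noncoding Gm14742 40.3 ± 0.781 CPM (at least 352-fold) and Gm21033 36.4 ± 1.48 CPM (at least 319-fold). Several are pseudogenes or predicted genes whose reads may belong to relatives. The largest falls were Gm18363 from 31.9 ± 6.36 to 0.505 ± 0.197 CPM (log2 -5.97, adjusted p = 6.6e-05), and Rln3. The latter encodes the peptide relaxin-3 and fell by a ratio of 0.0149 (counting interval 0.00179 to 0.0551, adjusted p = 0.00051). Ugt3a2, a glycosyltransferase gene, fell from 52.4 ± 3.11 to 1.33 ± 0.478 CPM (chr15:9335550-9370955; log2 -5.29, adjusted p = 0.0012). The others were Fam213b (log2 -5.17, adjusted p = 1.9e-05), Gm44454 (log2 -5.15, adjusted p = 0.028) and 6330410L21Rik (log2 -5.02, adjusted p = 0.0055). Fam213b overlaps Mmel1, Gm44454 is a microRNA gene inside Hist1h2ak and 6330410L21Rik is antisense to Egf, so all 3 are uncertain for want of strand. Gm44454 was lost without any of 3 libraries (adjusted p = 0.38 without control b, 0.14 without drug library a and 0.092 without b). 6330410L21Rik was lost without drug library a (adjusted p = 0.050).

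Pluripotency genes fell in wild-type cells. Tdgf1, a Nodal co-receptor gene, went from 404 ± 59.5 to 14 ± 2.46 CPM (chr9:110939603-110946158; log2 -4.85, edgeR adjusted p = 7.2e-06). Fgf4 fell from 162 ± 2.27 to 16.3 ± 2.68 CPM (log2 -3.31) and the transcription factor gene Esrrb from 447 ± 39.0 to 78.3 ± 13.7 CPM (chr12:86361117-86521628; log2 -2.51). Pou5f1, which encodes Oct4 and overlaps another gene, fell from 914 ± 20.8 to 151 ± 7.47 CPM (log2 -2.60). Of 24 naive pluripotency genes 19 fell and 1 rose, the same adjusted over the list alone (median log2 -2.09, camera adjusted p = 3.1e-15, adjusted p = 0.042 with an estimated correlation). Primed pluripotency genes moved both ways, with 2 of 13 up and 7 down (2 and 7 adjusted over the list alone, camera adjusted p = 0.20). Sox3 rose from 1.30 ± 0.466 to 7.98 ± 0.367 CPM (log2 2.61) and Lefty2 fell from 50.9 ± 3.88 to 12.3 ± 1.61 CPM (log2 -2.05).

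Genes of several lineages rose in wild-type cells without their lists being called as groups. Wnt3, a signal that patterns the primitive streak, went from 0.499 ± 0.283 to 45.8 ± 5.06 CPM (chr11:103774150-103817957; log2 6.52, edgeR adjusted p = 1.9e-05). Mesp1, a mesoderm factor, rose from 0 to 5.62 ± 0.799 CPM (at least 49.1-fold). Of 11 primitive streak and mesoderm genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.22). Trophectoderm genes had 11 of 18 up and 1 down (camera adjusted p = 0.086, or 0.028 with the replicate block). Primitive endoderm genes had 8 of 16 up and 1 down (camera adjusted p = 0.25). Neuroectoderm genes had 5 of 10 up and 1 down (adjusted p = 0.41, median log2 0.83 on counts and -0.21 on the 3 genes left on FPKM). Fibroblast genes had 6 of 10 up and 1 down (adjusted p = 0.33). Germline and meiosis genes split 3 up and 3 down of 16, with median, mean and test of differing sign (adjusted p = 0.94). The meiotic cohesin gene Rec8 rose from 6.72 ± 0.936 to 64.1 ± 6.67 CPM (log2 3.25) and Ddx4 fell from 12.7 ± 0.411 to 6.87 ± 0.157 CPM (log2 -0.89). Except for the streak genes, the counts in these 6 lists were the same adjusted over the list alone.

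Genes for dividing and for repairing DNA fell in wild-type cells. Gmnn, which limits replication origins, went from 126 ± 16.0 to 33.1 ± 3.89 CPM (log2 -1.93, edgeR adjusted p = 4.4e-05). Of 24 G1/S and DNA replication genes 18 fell and 1 rose (camera adjusted p = 7e-06, adjusted p = 0.34 with an estimated correlation). Xrcc5, the Ku80 gene of end joining, fell from 250 ± 22.1 to 62.8 ± 0.415 CPM (chr1:72307421-72394952; log2 -1.99). Of 23 DNA repair genes 13 fell and 2 rose (camera adjusted p = 0.0037, adjusted p = 0.38 with an estimated correlation). Ubtf, a factor for transcription of ribosomal DNA, fell from 198 ± 5.93 to 67.9 ± 0.487 CPM (chr11:102304560-102319742; log2 -1.54), and of 20 ribosome biogenesis genes 12 fell and 5 rose (camera adjusted p = 0.0025, adjusted p = 0.37 with an estimated correlation). G2/M and mitosis genes had 9 of 23 down and 2 up (camera adjusted p = 0.053, 0.023 with the replicate block and 0.059 with the block and the recovered Dux KO control). Cdk1 fell from 280 ± 12.8 to 149 ± 4.28 CPM (log2 -0.91), while Cenpe rose from 126 ± 6.99 to 218 ± 14.8 CPM (log2 0.79). Replication-dependent histone genes had 4 of 20 up and 2 down (camera adjusted p = 0.79). Adjusted over the list alone, none of these counts changed.

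Stress genes rose in wild-type cells. Fos went from 1.99 ± 0.512 to 25.9 ± 0.8 CPM (chr12:85473890-85477273; log2 3.70, edgeR adjusted p = 1e-05). Chac1, a glutathione-degrading enzyme gene, fell from 17.8 ± 0.264 to 1.11 ± 0.252 CPM. Of 18 stress and immediate early genes 11 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 0.51 with an estimated correlation). The call was lost without control a (adjusted p = 0.067) or drug library b (adjusted p = 0.079), with the replicate block (adjusted p = 0.059) and with the recovered Dux KO control (adjusted p = 0.051). Interferon genes had 9 of 18 up and 3 down (9 and 3 adjusted over the list alone, camera adjusted p = 0.30, median log2 2.75 on counts, 0.93 with zero groups at the floor and -0.06 on 7 genes on FPKM). Oas1a fell from 29 ± 0.192 to 4.57 ± 0.913 CPM (log2 -2.67). Apoptosis genes moved both ways, 7 of 18 up and 6 down, or 8 and 6 adjusted over the list alone. Median, mean and test differed in sign (adjusted p = 0.70, median log2 0.28 on counts and -0.17 on 11 genes on FPKM). The DNA fragmentation factor gene Dffb rose from 10.5 ± 0.337 to 75.6 ± 5.21 CPM (log2 2.85).

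Over all 28643 genes, 8297 rose and 6700 fell in wild-type cells by edgeR's quasi-likelihood test (55.3% up), 7042 and 4044 of them by more than 2-fold. On log2(FPKM + 1) limma called 3391 up and 4455 down (43.2% up) among genes of at least 1 FPKM in 2 libraries, and 8602 up and 4694 down (64.7% up) without that filter, so the balance turned on it. RLE scaling moved the median of all genes by 0.10 here, -0.12 in the p53 KO interaction, -0.11 in p53 KO under drug and -0.10 in Dux KO under drug. The authors' deposited table gave log2 2.65 for Mdm2, 8.57 for Zscan4c, 8.67 for Zfp352 and -2.48 for Esrrb in the same comparison. Of the 14160 genes called both here and in the authors' deposited table, 14160 had the same sign.

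The next question was what the drug does without p53. Interferon genes rose, with no called interaction (camera adjusted p = 0.40). The RNA sensor gene Ddx58 went from 17.8 ± 2.67 to 44.4 ± 1.44 CPM (chr4:40203773-40239828; log2 1.32, SE 0.19, edgeR adjusted p = 0.0039). Oasl2 rose from 0.595 ± 0.0886 to 2.98 ± 0.732 CPM (log2 2.32). Of 18 interferon genes 8 rose and 0 fell, or 14 and 0 adjusted over the list alone (median log2 1.89, camera adjusted p = 2.6e-06, adjusted p = 0.13 with an estimated correlation). The largest rises by the fitted log2 were C430002N11Rik, from 0 to 2.33 ± 0.843 CPM (at least 22.2-fold), and the interferon-induced GTPase genes Tgtp1 and Tgtp2. Tgtp1, which overlaps another gene, rose from 0.106 to 9.53 ± 5.70 CPM (log2 6.46), and its close relative Tgtp2 by a ratio of 88.8 (counting interval 24.2 to 739). Isg15 (ratio 83.8, counting interval 22.8 to 698, adjusted p = 0.019) was lost without p53 KO control 2 (adjusted p = 0.068) or drug library 1 (adjusted p = 0.063). Gm15848 (ratio 76.7, counting interval 20.9 to 639) was lost without control 1 (adjusted p = 0.063). The largest falls were Gm22489 (log2 -2.82, adjusted p = 0.0049), Gm26224 (log2 -2.49), Gm17590 (log2 -2.48), Hist1h2an (log2 -2.39) and Snord49b (log2 -2.36, adjusted p = 0.0064). Apart from the histone gene, these are small nucleolar or antisense RNA genes inside other genes and uncertain for want of strand. Hist1h2an was lost without control 2 (adjusted p = 0.091) or either drug library (0.072 and 0.059).

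Of the p53 targets in p53 KO cells, 8 of 40 rose and 3 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.53). Abhd4 rose from 17.8 ± 1.13 to 44.9 ± 16.7 CPM (log2 1.33, edgeR adjusted p = 0.0065). The kinase gene Plk2 rose from 1.77 ± 0.807 to 19 ± 15.9 CPM (chr13:110395046-110400844; log2 3.44). The p53 list was called up without control 1 (camera adjusted p = 0.033) or drug library 2 (adjusted p = 1.2e-05). Its direction turned without control 2 (adjusted p = 0.37) or drug library 1 (adjusted p = 0.20). Among 2-cell genes 3 of 47 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.12, 0.036 with the replicate block and 0.060 with the block and the recovered Dux KO control). Nat8f2 rose from 0.635 ± 0.239 to 2.89 ± 0.912 CPM (log2 2.19, adjusted p = 0.012), a call lost without control 2 (adjusted p = 0.053). The 2-cell list moved the other way without drug library 1 (adjusted p = 0.0047) and up without drug library 2 (adjusted p = 2.9e-25), so the result rested on p53 KO drug library 1. Outside multigene families 2 of 9 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.086, or 0.019 with the block). Duxf3 was not called (log2 3.27, adjusted p = 0.077). It was called with the block (log2 2.96, adjusted p = 0.016) and without drug library 2 (log2 4.02, adjusted p = 0.020). Without control 2 the remaining control has 0 counts, which leaves the ratio undefined.

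On counts, naive pluripotency, cell-cycle and ribosome genes fell without p53 as well, and on FPKM most of these falls were not called. Fgf4 went from 173 ± 6.28 to 84.4 ± 5.89 CPM (log2 -1.04, edgeR adjusted p = 0.0050). Of 24 naive genes 13 fell and 1 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.072 with an estimated correlation). Of 23 G2/M genes 9 fell and 0 rose, or 11 and 0 adjusted over the list alone (camera adjusted p = 3.8e-05, adjusted p = 0.45 with an estimated correlation). G1/S genes had 4 of 24 down and 0 up, or 5 and 0 adjusted over the list alone (camera adjusted p = 1.8e-05, adjusted p = 0.36 with an estimated correlation). Among DNA repair genes 6 of 23 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.40 with an estimated correlation). Xrcc5 fell from 255 ± 59.8 to 118 ± 19.5 CPM (log2 -1.11). Npm1 fell from 839 ± 73.3 to 331 ± 100 CPM (log2 -1.34). Of 20 ribosome biogenesis genes 7 fell and 1 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00095, adjusted p = 0.37 with an estimated correlation). Histone genes had 2 of 20 down and 0 up, or 0 and 0 adjusted over the list alone (median log2 -1.09, camera adjusted p = 0.00074, adjusted p = 0.45 with an estimated correlation). On log2(FPKM + 1) limma called 1 up and 5 down of 24 naive genes (median log2 -0.25), 0 and 0 of 23 G2/M (-0.01), 1 and 0 of 22 G1/S (-0.02), 2 and 2 of 22 repair (0.05) and 3 and 3 of 20 ribosome genes (-0.02).

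Primitive endoderm genes rose without p53, 6 of 16 up and 1 down, or 7 and 1 adjusted over the list alone. The camera adjusted p was 0.014, 0.49 with an estimated correlation and 0.94 for the interaction. The call was lost without control 2 (adjusted p = 0.15). Lamb1 rose from 31.9 ± 6.02 to 62.8 ± 25.5 CPM (log2 0.98, edgeR adjusted p = 0.028) and Sparc from 188 ± 45.4 to 303 ± 51 CPM (log2 0.69, adjusted p = 0.030). Lamb1 was lost without control 1 (adjusted p = 0.11) or drug library 2 (0.077), and Sparc without control 2 (0.11) or drug library 1 (0.092). Primed pluripotency genes had 4 of 13 up and 0 down, the same adjusted over the list alone (camera adjusted p = 0.074, or 0.0047 with the replicate block). Lefty1 rose from 6.01 ± 4.07 to 35.1 ± 2.82 CPM (log2 2.55). Stress genes went both ways, 4 of 18 up and 5 down (camera adjusted p = 0.68, with median, mean and test of differing sign). Egr1 rose from 0.495 ± 0.230 to 3.21 ± 0.612 CPM (log2 2.69). Ier3 fell from 40.7 ± 8.65 to 9.69 ± 3.56 CPM (log2 -2.07) and Atf4 from 231 ± 34.7 to 123 ± 2.39 CPM (log2 -0.91). Over all genes 2668 rose and 2318 fell (53.5% up), against 1780 and 449 on log2(FPKM + 1) by limma (79.9% up, or 87.8% without the FPKM filter). With the p53 KO libraries fitted alone edgeR called 0 of 23041 genes (5183 at an unadjusted p under 0.05). DESeq2 on all libraries called 6646 and edgeR with the replicate block 10876.

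Whether the response differs without p53 was tested as an interaction over the 4 groups. Mdm2 went from 46.9 ± 3.21 to 61.1 ± 12.3 CPM in p53 KO cells, so its change differed from that of wild-type cells by log2 -2.23 (SE 0.21, edgeR adjusted p = 0.00039). Ercc5 (log2 -1.33), Ppm1d (log2 -1.14) and Cdkn1a, the p21 gene (log2 -2.14, overlapping another gene), differed likewise. Of 40 p53 targets 16 responded less and 0 more, or 18 and 0 adjusted over the list alone (median log2 -1.02, camera adjusted p = 3e-07, adjusted p = 0.56 with an estimated correlation). The 2-cell genes differed most. Zfp352 went from 1.47 ± 0.0969 to 1.92 ± 1.01 CPM in p53 KO cells (interaction log2 -8.22, adjusted p = 0.00041) and Zscan4a from 5.50 ± 1.27 to 8.60 ± 5.50 CPM (interaction log2 -8.85, adjusted p = 0.00034). Of 47 members 44 responded less and 0 more, or 45 and 0 adjusted over the list alone (median log2 -6.99, or -6.76 at the floor, camera adjusted p = 3.6e-54, adjusted p = 0.25 with an estimated correlation). So did 7 of the 9 outside multigene families, or 8 adjusted over the list alone (camera adjusted p = 6.8e-12, adjusted p = 0.34 with an estimated correlation). The difference for Duxf3 in p53KO interaction tests was not called (log2 -4.27 with wild-type controls at the floor, adjusted p = 0.080). It was called with the replicate block (adjusted p = 0.014), without p53 KO control 1 (adjusted p = 0.031) and without drug library 1 (adjusted p = 0.015). Without control 2 it is undefined, since the remaining p53 KO control has 0 counts.

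Pluripotency genes fell less without p53. Tdgf1 went from 395 ± 34.0 to 206 ± 30.5 CPM (interaction log2 3.92, edgeR adjusted p = 0.00034). Tcl1 had an interaction log2 of 4.21 (adjusted p = 0.00050). Of 24 naive genes 14 differed upward and 1 downward, or 15 and 1 adjusted over the list alone (camera adjusted p = 1e-10, adjusted p = 0.052 with an estimated correlation). So did 5 of 13 primed genes, or 8 adjusted over the list alone (camera adjusted p = 0.0044, adjusted p = 0.25 with an estimated correlation). Lefty1 (log2 4.39) and Lefty2 (log2 3.69) were among them. G1/S genes had 7 up and 1 down of 24, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.55 with an estimated correlation). Stress genes had 1 up and 7 down of 18, the same adjusted over the list alone (camera adjusted p = 0.00047, adjusted p = 0.36 with an estimated correlation). Fos differed by log2 -2.49 and Chac1 by 2.58. Histone genes had 0 up and 5 down of 20, the same adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.56 with an estimated correlation). That call was lost without p53 KO control 1 (adjusted p = 0.067). In all, 2837 genes differed upward and 2961 downward (48.9% up), against 3153 and 1959 on log2(FPKM + 1) by limma (61.7% up, or 46.4% without the FPKM filter), 39.9% up with RLE scaling and 41.7% by DESeq2. The total of 5798 fell to 3181 or 3077 without wild-type control a or b and to 3562 or 3100 without wild-type drug library a or b. It was 10796 with the replicate block.

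Compared directly under drug, p53 KO cells stood below wild-type cells in 34 of 40 p53 targets and above in 1 (34 and 1 adjusted over the list alone, camera adjusted p = 9.2e-23, adjusted p = 0.36 with an estimated correlation). Trp53inp1 stood at 64.7 ± 9.24 against 767 ± 32.3 CPM (chr4:11156431-11174379; log2 -3.57, edgeR adjusted p = 7.6e-06). All 47 2-cell genes were lower (47 adjusted over the list alone, median log2 -5.08, camera adjusted p = 9.6e-22, adjusted p = 0.36 with an estimated correlation). So were all 9 outside multigene families (9 adjusted over the list alone, camera adjusted p = 7e-06, adjusted p = 0.37 with an estimated correlation). Duxf3 was lower too (log2 -3.24, adjusted p = 0.022). It was not called by DESeq2 (adjusted p = 0.29) or without wild-type drug library a (adjusted p = 0.079) or b (adjusted p = 0.089). Naive genes were higher in 17 of 24 and lower in 2, the same adjusted over the list alone (camera adjusted p = 3.1e-08, adjusted p = 0.070 with an estimated correlation). G1/S genes were higher in 13 of 24 and lower in 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.0090, adjusted p = 0.49 with an estimated correlation). The largest differences downward by the fitted log2 were Cbln2, a synapse organiser gene, at 0 against 14.1 CPM (at least 134-fold lower, adjusted p = 5.5e-05), and Gm14974 (at least 95.7-fold lower). Ces2e (ratio 0.000587, counting interval 7.11e-05 to 0.00212), Gm32369 (at least 48-fold lower) and Astl followed. Astl, an oocyte protease gene, stood at 0 against 4.80 CPM (at least 45.5-fold lower). Upward they were AC078895.1 (at least 21.2-fold higher), Nutm1 (ratio 225, counting interval 39.9 to 8920), Grrp1 at 7.82 against 0.0654 CPM (log2 6.83), Rln3 (ratio 110, counting interval 30 to 912) and Fgg (log2 7.73). Fgg was lost without 3 of the 4 libraries in turn. In total 6221 genes were higher and 6306 lower (49.7% up), against 5234 and 2791 on log2(FPKM + 1) by limma (65.2% up, or 52.1% without the FPKM filter), 43.4% up with RLE scaling and 45.4% by DESeq2, and 8184 in all were left without wild-type drug library b.

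Without drug, p53 KO cells had lower levels of p53 targets than wild-type cells. Trp53inp1 stood at 36.1 ± 6.94 against 274 ± 15.7 CPM (log2 -2.93, SE 0.17, edgeR adjusted p = 0.00026). Zmat3 stood at 25.4 ± 2.59 against 97.4 ± 7.24 CPM (log2 -1.94, adjusted p = 0.0011). Of 40 members 18 were lower and 0 higher, or 30 and 0 adjusted over the list alone (median log2 -1.15, camera adjusted p = 3e-56, adjusted p = 0.25 with an estimated correlation). The 2-cell genes were higher instead, with Zscan4a called (log2 3.77, adjusted p = 0.024), Zscan4c at 9.22 ± 0.560 against 1.33 ± 0.234 CPM (adjusted p = 0.060) and Zfp352 (adjusted p = 0.070). Of 47 members 1 was higher and 0 lower, or 16 and 1 adjusted over the list alone (median log2 2.11, or 1.81 at the floor, camera adjusted p = 1.2e-25, adjusted p = 0.37 with an estimated correlation). For the 9 outside multigene families the counts were 0 and 0, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.56 with an estimated correlation). The damage-inducible Ddit4l went the other way, 0.961 ± 0.606 against 13.8 ± 1.18 CPM (adjusted p = 0.071). The largest calls upward were Zscan4-ps1 (log2 3.88), Zscan4a, Fcrl5 (log2 3.49), Lhfpl5 (log2 3.12) and Zscan4-ps2 (log2 3.01). All of them were lost without either wild-type control (Zscan4a adjusted p = 0.25 and 0.21). Downward they were Pla2g2f (ratio 0.0163, counting interval 0.00195 to 0.0604, adjusted p = 0.062 with the recovered Dux KO control), Inka2, 9530053A07Rik (log2 -5.49), Slc5a1 and Cpz. Slc5a1, a sodium-glucose transporter gene, stood at 0.392 against 15.6 CPM (chr5:33104219-33162870; log2 -5.32). Without wild-type control a or b the last 4 were lost too (Slc5a1 adjusted p = 0.081 and 0.072).

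Stress genes were higher in p53 KO controls, 1 of 18 called and 8 adjusted over the list alone (median log2 0.63, camera adjusted p = 1.2e-06, adjusted p = 0.25 with an estimated correlation). Gadd45b stood at 80.2 ± 12.9 against 27.9 ± 3.88 CPM (log2 1.52, edgeR adjusted p = 0.013). Primitive endoderm genes were lower, 0 of 16 called and 3 adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation, and 0.17 with the replicate block). Interferon genes had a median log2 of 0.69, or 0.19 with zero groups at the floor. Of 18 members 0 were higher and 1 lower, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.37 with an estimated correlation, and 0.097 with the block). The germline helicase gene Ddx4 stood at 32.7 ± 4.44 against 12.7 ± 0.411 CPM (log2 1.36, adjusted p = 0.0090). Without wild-type control a or b, neither gene was called (Gadd45b adjusted p = 0.20 and 0.11, Ddx4 0.15 and 0.12). Over all genes 40 were higher and 214 lower (15.7% up), against 5 and 38 on log2(FPKM + 1) by limma (11.6% up, or 24.4% without the FPKM filter). The block, for line 1, gave 57.2% up. By chromosome, genes on chromosome 8 stood above those of wild-type controls by a median log2 of 0.43 in p53 KO control 1, where the wild-type pair differed by at most 0.05 on any chromosome. The total of 254 fell to 30 or 38 without wild-type control a or b and to 157 without p53 KO control 1, and was 1312 by DESeq2 (41.8% up) and 5482 with the replicate block, where the balance turned (57.2% up).

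**Figure D2:**
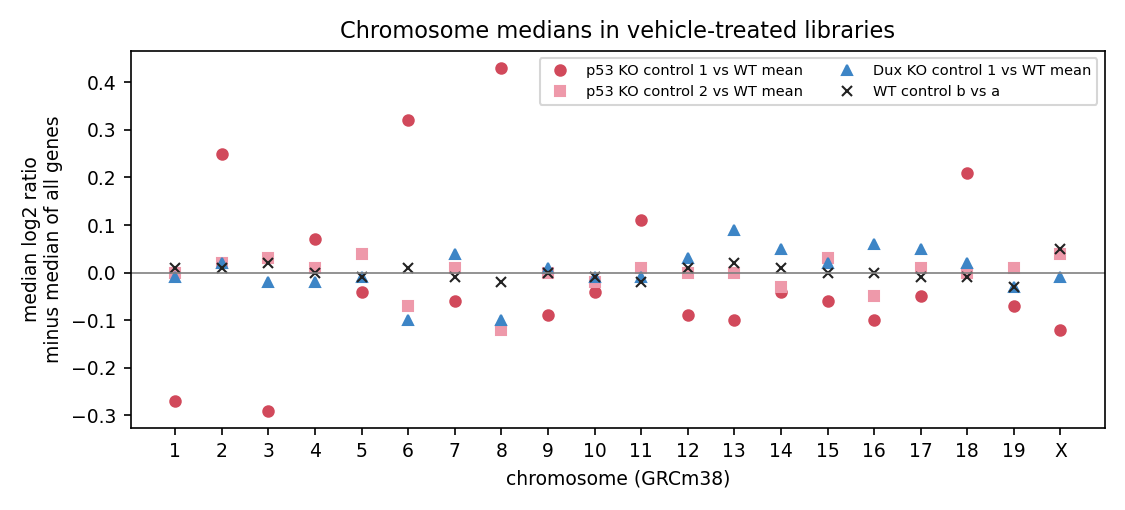
Median log2 ratio of each chromosome's genes to the wild-type control mean, less the median of all genes, for p53 KO controls 1 and 2 and Dux KO control 1, with wild-type control b against a.

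The same question was asked of Dux: what does the drug do in cells that lack it? The p53 targets rose as a group. Mdm2 went from 110 to 657 ± 39.1 CPM (log2 2.58, SE 0.20, edgeR adjusted p = 0.00016). Abhd4 rose from 41.8 to 286 ± 17.2 CPM (log2 2.77). Of 40 members 26 rose and 0 fell, or 28 and 0 adjusted over the list alone (median log2 1.49, camera adjusted p = 1.4e-11, adjusted p = 0.49 with an estimated correlation). Of 47 2-cell genes only 2 rose and 0 fell, or 1 and 0 adjusted over the list alone. The list was not called (median log2 0.00, or -0.07 with zero groups at the floor, camera adjusted p = 0.75, with median, mean and test of differing sign). Both are on the list outside multigene families, where 2 of 9 rose, the same adjusted over the list alone (camera adjusted p = 0.20). Sp110, which overlaps another gene, rose from 0 to 2.20 ± 0.573 CPM (at least 37.7-fold), and Ddit4l from 6.64 to 74.9 ± 6.36 CPM (log2 3.50, adjusted p = 0.024). Ddit4l was lost without drug library 1 (adjusted p = 0.070) or 2 (adjusted p = 0.069). Zscan4a, Zscan4c and Zfp352 had 0 counts in both Dux KO drug libraries. The largest rises by the fitted log2 were Eef1a2, a translation factor gene, from 0 to 64.7 ± 8.99 CPM (chr2:181147653-181157014; at least 1110-fold, adjusted p = 0.0021). Next were Slc5a4a (at least 411-fold), Dmkn (at least 380-fold), Gm15635 (at least 280-fold) and Otof (at least 249-fold). The largest falls were Pou4f2 (log2 -5.61), Etv1 from 15.1 to 0.427 CPM (log2 -5.13, adjusted p = 0.00016), Gm5454 (log2 -4.93), 6330410L21Rik (log2 -4.83, lost without single libraries, adjusted p = 0.086 and 0.098) and Slc7a3. This arginine transporter gene fell from 115 to 4.29 ± 0.398 CPM (log2 -4.75, adjusted p = 8e-05).

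Naive pluripotency, replication and ribosome genes fell in Dux KO cells, and repair genes on counts alone. Nr0b1 went from 91.2 to 7.29 ± 1.76 CPM (log2 -3.64, edgeR adjusted p = 0.00027). Of 24 naive genes 17 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.8e-15, adjusted p = 0.042 with an estimated correlation). Of 24 G1/S genes 14 fell and 1 rose, or 17 and 1 adjusted over the list alone (camera adjusted p = 0.00020, adjusted p = 0.37 with an estimated correlation). Xrcc5 fell from 223 to 87.1 ± 1.25 CPM (log2 -1.36) while Xrcc1 rose from 92.9 to 279 ± 3.24 CPM (log2 1.59). Of 23 repair genes 9 fell and 1 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 0.51 with an estimated correlation, and 0.066 with the recovered control). Ubtf fell from 236 to 77.7 ± 3.05 CPM (log2 -1.60). Among ribosome biogenesis genes 12 of 20 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.6e-07, adjusted p = 0.25 with an estimated correlation). Histone genes had 8 of 20 down and 0 up, or 13 and 0 adjusted over the list alone (median log2 -2.32, or -2.19 at the floor, camera adjusted p = 5.3e-05, adjusted p = 0.37 with an estimated correlation). G2/M genes had 8 of 23 down and 0 up, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.053, or 0.028 with the replicate block). On log2(FPKM + 1) limma called 0 up and 12 down of 24 naive (median log2 -0.71), 1 and 9 of 22 G1/S (-0.39), 3 and 3 of 22 repair (-0.08), 2 and 12 of 20 ribosome (-0.62) and 2 and 3 of 23 G2/M genes (-0.06).

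Stress genes and some lineage genes rose in Dux KO cells, in lists whose calls depended on the setting. Wnt3 went from 0.194 to 33.9 ± 5.14 CPM (log2 7.42, edgeR adjusted p = 0.00027) and Lhx1 from 0 to 4.21 ± 0.186 CPM (at least 72.3-fold). Of 11 streak and mesoderm genes 3 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.34 with an estimated correlation). The call was lost without drug library 2 and with the replicate block, which both leave library 1 of each group. Trophectoderm genes had 5 of 18 up and 1 down, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.48 with an estimated correlation). They lost the call without drug library 2, with the block and with the recovered control (adjusted p = 0.24). Germline genes had 5 of 16 up and 0 down, the same adjusted over the list alone (camera adjusted p = 0.044, adjusted p = 0.64 with an estimated correlation). This too was lost without drug library 2, with the block and with the recovered control (adjusted p = 0.18). Neuroectoderm genes had 1 of 10 up and 3 down (median log2 -0.86, camera adjusted p = 0.34). Rec8 rose from 3.96 to 54.2 ± 3.41 CPM (log2 3.77). Of 18 stress genes 9 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.45 with an estimated correlation, and 0.076 with the recovered control). Over all genes 4156 rose and 3422 fell (54.8% up), against 3061 and 1895 on log2(FPKM + 1) by limma (61.8% up, or 75.2% without the FPKM filter). The total of 7578 fell to 5002 or 4291 without drug library 1 or 2, and was 9531 with the recovered control library.

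**Figure D3:**
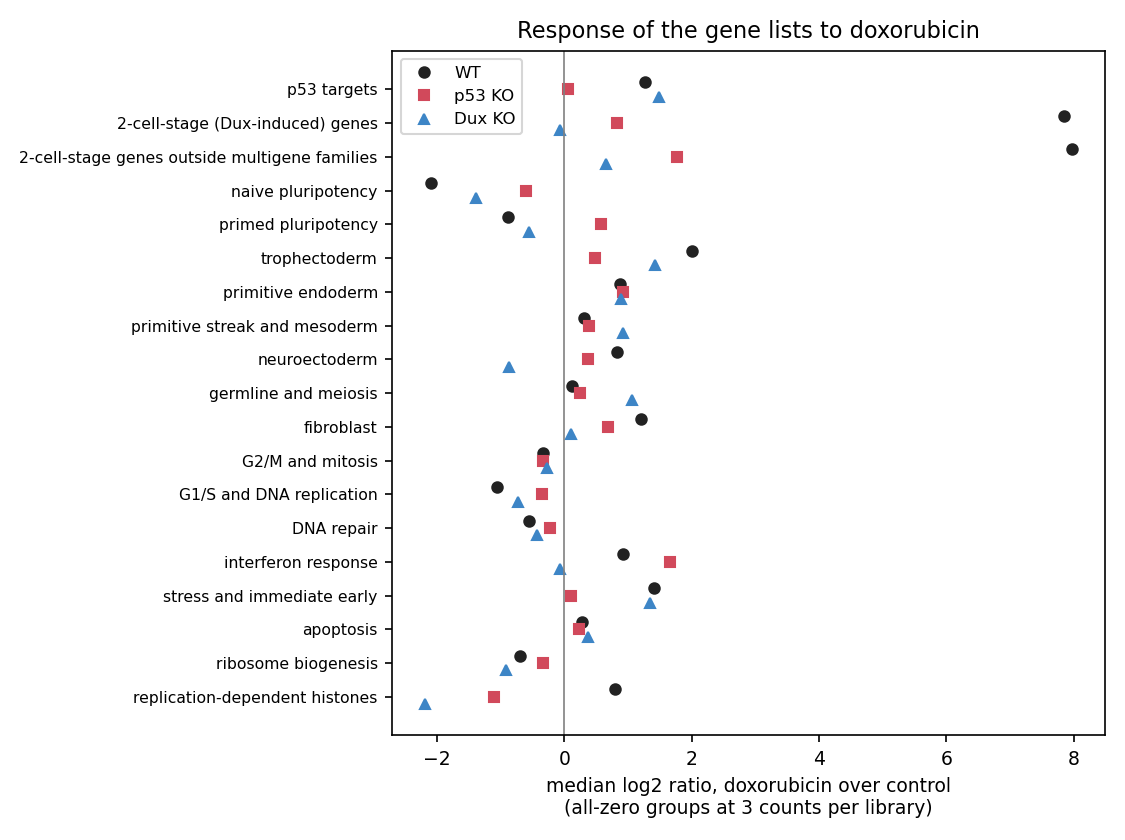
Median log2 ratio of drug to control over each of 19 gene lists in wild-type, p53 KO and Dux KO cells, with groups at 0 counts set to 3 counts per library.

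Whether the response differs without Dux was tested in the same way. Tdgf1 fell from 568 to 194 ± 63.5 CPM, less than in wild-type cells (interaction log2 3.31, SE 0.39, edgeR adjusted p = 0.0024). So did Fgf4, from 214 to 81.8 ± 15.1 CPM (interaction log2 1.92, adjusted p = 0.0047). Of 24 naive genes 5 differed upward and 3 downward, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.35 with an estimated correlation). The call was lost with the replicate block and without wild-type control a, though not with the block and the recovered control (adjusted p = 0.0038). Arg2, which overlaps another gene, stood at 0.272 and 0.427 ± 0.0371 CPM in Dux KO control and drug libraries (interaction log2 -7.31, adjusted p = 0.0017). Of 47 2-cell genes 3 differed downward and 0 upward, or 4 and 0 adjusted over the list alone (median log2 -7.77, or -7.73 at the floor, camera adjusted p = 0.00051, adjusted p = 0.65 with an estimated correlation, and 0.33 by fry). Outside multigene families the counts were 2 and 0 of 9 (camera adjusted p = 0.053). On log2(FPKM + 1), with control 2 included, 42 of 43 members and 7 of 8 outside families were lower. Most of these genes had no counts in either Dux KO group, so the fit on counts leaves their ratio undefined. The comparison under drug is the more telling one for them. No p53 target differed by edgeR (0 of 40, also adjusted over the list alone, camera adjusted p = 0.18). With the replicate block, Dux KO rests on library 1 of each group unless the control is recovered. With both, 5 differed upward and 1 downward (camera adjusted p = 0.23). Histone genes differed downward, 3 of 20 or 9 adjusted over the list alone (median log2 -3.16, or -2.77 at the floor, camera adjusted p = 2.6e-08, adjusted p = 0.34 with an estimated correlation).

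Neuroectoderm genes responded less without Dux, 2 of 10 lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.34 with an estimated correlation, and 0.085 with the recovered control). Germline genes responded more, 1 of 16 higher and 0 lower, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.60 with an estimated correlation, 0.22 by fry, 0.074 without drug library 2 and 0.083 with the recovered control). Sizes of the largest interactions are given with groups below 3 counts per library set to that floor, which covers every one but Slamf8 and Igll1. Upward they were Csf1 (log2 3.01), Slamf8 (log2 5.66), Bpifb4 (log2 3.95), Igll1 (log2 4.25) and Disp3 (log2 3.77), and all lost their calls without any 1 of the libraries. Downward they were Gm16239 (log2 -10.21), Gm3669 (log2 -7.06), Gm12823 (log2 -8.41), Gm2075 (log2 -7.10) and Gm26918 (log2 -7.06), of which Gm16239 and Gm26918 kept theirs. These 5 had between 0.0388 and 0.311 CPM in the Dux KO control, and Gm16239, Gm12823 and Gm26918 lie antisense to other genes, so their sizes are uncertain. Over all genes 601 differed upward and 903 downward (40% up), against 852 and 944 on log2(FPKM + 1) by limma (47.4% up, or 33.1% without the FPKM filter). The total of 1504 fell in every fit without 1 library, to 460 or 362 without wild-type control a or b, 789 or 398 without wild-type drug library a or b and 569 or 509 without Dux KO drug library 1 or 2. DESeq2 gave 3453 (46.7% up), and the balance turned with the block (5892, 59% up) and with only the groups compared (56.4% up).

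Compared directly under drug, 2-cell genes stood lower in Dux KO than in wild-type cells. Zscan4c stood at 0 against 496 ± 66.4 CPM in wild-type cells (at least 8920-fold lower, edgeR adjusted p = 3.3e-05) and Zfp352 at 0 against 75.7 ± 14.6 CPM (at least 1360-fold lower). Usp17le stood at 0.128 ± 0.128 against 269 ± 39.5 CPM (log2 -10.98) and Nat8f2 at 0.525 ± 0.209 against 20.7 ± 5.86 CPM (log2 -5.29). Ddit4l, at 79.4 and 70.4 against 218 and 232 CPM, was the member not called. Duxf3 was at least 398-fold lower (adjusted p = 0.0015). Of 47 members 46 were lower and 0 higher, or 47 and 0 adjusted over the list alone (median log2 -12.41, or -9.95 at the floor, camera adjusted p = 2e-69, adjusted p = 0.25 with an estimated correlation). So were 8 of the 9 outside multigene families, or 9 adjusted over the list alone (camera adjusted p = 2.7e-13, adjusted p = 0.34 with an estimated correlation). The p53 targets had 5 of 40 higher and 2 lower, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.49, median log2 0.09 with TMM and -0.02 with RLE). Mdm2 was lower (log2 -0.53, adjusted p = 0.025), a call lost without any 1 of the 4 libraries (adjusted p from 0.076 to 0.15). The largest differences downward by the fitted log2 were Gm21293, at 0 against 561 ± 51.2 CPM (at least 10100-fold lower), and the Zscan4 genes c, f (at least 8830-fold), d (at least 7070-fold) and e (at least 5570-fold). Upward they were Aldoart1, a testis aldolase gene, at 20.5 ± 3.88 against 0.490 CPM (chr4:72850583-72852634; log2 5.38, adjusted p = 4.1e-05). Others were Aurkc (log2 4.87, adjusted p = 0.056 without wild-type drug library b), Golt1a, Gm28040 and Slamf8, at 3.74 against 0.130 CPM (log2 4.80).

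Naive genes stayed higher under drug in Dux KO than in wild-type cells, 14 of 24 higher and 3 lower, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.25 with an estimated correlation). Esrrb stood at 252 ± 24.1 against 78.3 ± 13.7 CPM (log2 1.68). Trophectoderm genes were lower in 9 of 18 and higher in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.41 with an estimated correlation). Rhox9 stood at 5.08 ± 0.224 against 16.7 ± 1.38 CPM (log2 -1.71). Neuroectoderm genes were lower in 4 of 10 and higher in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.35 with an estimated correlation, and 0.051 with the replicate block). Histone genes were lower in 12 of 20, or 16 adjusted over the list alone (median log2 -2.94, or -2.76 at the floor, camera adjusted p = 0.00052, adjusted p = 0.48 with an estimated correlation). Over all genes 4456 were higher and 4162 lower (51.7% up), against 3817 and 1570 on log2(FPKM + 1) by limma (70.9% up, or 51.1% without the FPKM filter), and the balance turned with RLE scaling (43.5% up) and by DESeq2 (46% up). The total of 8618 fell to 5000 or 3731 without wild-type drug library a or b and to 3961 or 4792 without Dux KO drug library 1 or 2.

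Without drug, the Dux KO library had no counts for Zscan4c against 1.33 ± 0.234 CPM in wild-type controls (at least 22.8-fold lower, edgeR adjusted p = 0.077). Of 47 2-cell genes 0 were called, or 19 lower and 0 higher adjusted over the list alone (median log2 -4.89, or -2.18 at the floor, camera adjusted p = 6.9e-22, adjusted p = 0.38 with an estimated correlation). Of the 9 outside multigene families 0 were called (camera adjusted p = 0.0031, adjusted p = 0.56 with an estimated correlation). Germline genes were lower, 1 of 16 or 9 adjusted over the list alone (median log2 -1.48, camera adjusted p = 4.8e-09, adjusted p = 0.37 with an estimated correlation). Trophectoderm genes were lower too, 2 of 18, the same adjusted over the list alone (median log2 -1.24, or -0.97 at the floor, camera adjusted p = 0.00045, adjusted p = 0.34 with an estimated correlation). The same held for primitive endoderm genes, 1 of 16, the same adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.55 with an estimated correlation, 0.061 with the replicate block and 0.0049 with the block and the recovered control). The p53 targets were not called (0 of 40, camera adjusted p = 0.098). With the block they were lower (adjusted p = 0.0024, 13 lower and 3 higher). The largest calls upward were Gm22009, Gm7676, Aldoart1, at 44.7 against 3.79 ± 1.02 CPM (log2 3.56, adjusted p = 0.016), Gm11836 and Dnase1l3. Downward they were Gm773, Usp26, at 0.272 against 19.2 CPM (log2 -6.12), Magea2, at 0.214 against 11.5 CPM, Rhox5 and 1700108F19Rik. The homeobox gene Rhox5 stood at 2.14 against 60.1 ± 5.17 CPM (chrX:37804842-37808876; log2 -4.81, adjusted p = 0.030). In total 188 genes were higher and 99 lower (65.5% up), against 331 and 58 on log2(FPKM + 1) by limma (85.1% up, or 82.7% without the FPKM filter) and 44.6% up by DESeq2. With a single Dux KO library every one of these calls was lost without either wild-type control. EdgeR then called 0 genes (3492 at an unadjusted p under 0.05 without control a and 3340 without b), where DESeq2 on all libraries called 2143.

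The responses of the genotypes overlapped. Of the genes that rose in p53 KO cells 1829 also rose in wild-type cells (68.6%, 773 expected, odds ratio 6.57) and 111 fell there. Of those that fell in p53 KO cells 1753 also fell in wild-type cells (75.6%, 542 expected, odds ratio 13.4) and 137 rose. Dux KO cells shared 3478 rises (83.7%, 1204 expected, odds ratio 20.9) and 2663 falls (77.8%, 800 expected, odds ratio 18.4) with wild-type cells, while 124 and 23 went the opposite way. No control library was shared between the responses. Genes within 1 response are not independent of each other, so the odds ratios describe these gene sets and no p is given.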

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

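Interaction tests in this part were chosen before the data were examined. Tests weighing the 2-cell genes of p53 KO libraries came after the result was seen. Each result is a tested difference between the wild-type and a knockout's response. Without p53, 5798 genes differed by edgeR. The lists that differed were p53 targets (camera adjusted p = 3e-07), 2-cell genes (3.6e-54), 2-cell genes outside multigene families (6.8e-12), naive pluripotency (1e-10), primed pluripotency (0.0044), G1/S and DNA replication (0.020), stress and immediate early (0.00047) and histones (0.012). With an estimated correlation none was called (adjusted p = 0.56, 0.25, 0.34, 0.052, 0.25, 0.55, 0.36 and 0.56 in that order). Fry gave 0.059 for p53 targets. The largest single-gene differences by the fit were Nutm1 (log2 5.07), Grrp1 (5.68), Gm18363 (6.09), Rln3 (4.49) and Nkx1-2 (5.94) upward, and Gm7957 (-8.03), Gm6346 (-7.47), Gm6348 (-7.44), Gm16429 (-6.98) and Gm14974 (-6.45) downward. All but Gm18363 have a group below 3 counts per library, set to that floor, so sizes depend on it.

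Without Dux, 1504 genes differed by edgeR from the wild-type response. Lists that differed were 2-cell genes (camera adjusted p = 0.00051), naive pluripotency (0.028), neuroectoderm (0.018), germline and meiosis (0.015) and histones (2.6e-08). None was called with an estimated correlation (adjusted p = 0.65, 0.35, 0.34, 0.60 and 0.34 in that order), and fry gave 0.33 for 2-cell and 0.22 for germline genes. Single genes were Csf1 (log2 3.01), Slamf8 (5.66), Bpifb4 (3.95), Igll1 (4.25) and Disp3 (3.77) upward, and Gm16239 (-10.21), Gm3669 (-7.06), Gm12823 (-8.41), Gm2075 (-7.10) and Gm26918 (-7.06) downward, again at the floor except for Slamf8 and Igll1.

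The 2-cell genes had a median of 1.75% and 1.56% of the drug-treated wild-type level in p53 KO controls, against 0.27% and 0.36% in wild-type controls. RNA or reads carried over from drug-treated wild-type libraries would lift p53 targets by the same share. But 4 of 21 (Fas, Plk2, Ephx1 and Zfp365) had an unhalved-count upper bound below it in both controls. Reads shared among gene copies as the whole cause would not lift genes without copies. In 7 members under 10% of 50-base words lie in annotated transcripts of other genes. Of these Zfp352, Tmem92 and Ubtfl1 stood above both wild-type controls in both libraries, though not called by edgeR. Their p (binomial on pooled halved counts, under 0.05 over 7) ignores spread between libraries. Ddit4l stood below and 3 were too low to decide. In p53 KO drug library 1 the median was 4.72%, a median gain of 2.91% over control 1. Carried-over RNA as the whole cause would bring every gene of drug-treated wild-type cells to that share. Of 138 other genes over 10 CPM there and under 0.5% of that in p53 KO controls, 21.7% had their upper counting bound below it, though their median was 3.46% against 0.63% in drug library 2. Carried-over RNA as part or all of the rise in these controls or that library stays open. So does low Dux-linked transcription in p53 KO cells, which was not tested.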

How the results depend on the processing

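The tests with recovered counts, with the copied column and without overlapping genes were chosen only after the data were seen. All other settings were fixed before. Over all settings, 83 of 158 counts of calls stayed within 1.5 times and 75 moved. Of 445 list tests 366 kept their side, 71 lost and 5 gained a call and 3 reversed. Of 8629 named-gene tests 7560 kept their side, 961 lost and 85 gained a call and 23 reversed, and of 16 overlaps 10 were kept. Of 95 named genes called in the wild-type response 87 were called in every fit without 1 library, against 42 of 74 in p53 KO cells, 64 of 82 in Dux KO cells, 59 of 79 and 5 of 30 in the interactions, 6 of 23 and 0 of 16 in controls, and 83 of 92 and 53 of 86 under drug. Depth differed between genotypes. Besides the changes printed here and beside each result, the replicate block changed no other call of a list or targeted gene, and it kept the calls of named genes except 1 of 82 in the Dux KO response and 1 of 92 in p53 KO under drug. Unless stated, the cause of a change was not tested.

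DESeq2 called 1312 genes in p53 KO controls, 2143 in Dux KO controls and 3453 in the Dux KO interaction. With DESeq2 and with RLE scaling Rln3 turned to log2 -0.01 in the p53 KO response, and Trp53 to -0.08 in Dux KO under drug. A log2 change above 1 was met by 2742 genes of the p53 KO response, fewer by construction.

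Limma on log2(FPKM + 1), which tests fewer genes, called 7846 in the wild-type, 2229 in the p53 KO and 4956 in the Dux KO response, 43 in p53 KO controls, 8025 in p53 KO and 5387 in Dux KO under drug. With log2(FPKM + 0.1) the counts were 7969, 2281, 4845, 111, 7954 and 5227. Without the FPKM filter the balance of rises and falls differed as given beside each result, and the counts were 3725 in the Dux KO interaction and 41 in p53 KO controls, and Disp3 turned to log2 -0.02 in the Dux KO interaction.

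With only the groups compared, fewer libraries set the spread: 0 genes were called in the p53 KO response, 12208 in the Dux KO response, 7565 in the Dux KO interaction, 25 in p53 KO controls, 9182 in Dux KO controls and 14286 in Dux KO under drug, and Rln3 turned to -0.04 in the p53 KO response. Leaving overlapping genes out of the counts left 6751, 2094 and 3381 in the wild-type, p53 KO and Dux KO responses, 2658 and 641 in the p53 KO and Dux KO interactions, 124 and 128 in controls and 5761 and 4163 under drug, by construction.

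The replicate block gave 10876 in the p53 KO response, 10796 in the p53 KO interaction, 5892 in the Dux KO interaction, 5482 in p53 KO controls and 5362 in Dux KO controls. Shared between wild-type and p53 KO responses were 3994 rises and 3469 falls with the block. It also called G2/M genes in p53 KO controls (adjusted p = 0.030), stress genes in Dux KO controls (0.045), primed (0.0046) and interferon genes (0.039) in p53 KO under drug, and germline (0.013) and ribosome genes (0.018) in Dux KO under drug. Trp53 was called with the block in the wild-type response (log2 -0.40, adjusted p = 0.0080), the Dux KO response (-0.84, 0.0011), the p53 KO interaction (0.65, 0.0068), Dux KO controls (0.46, 0.031) and p53 KO under drug (-0.56, 0.0024). The 2-cell list in the p53 KO response reached adjusted p = 0.036 and the p53 targets in the Dux KO interaction 0.030. With the block and the recovered counts several of these were lost: G2/M genes in p53 KO controls (0.052), stress genes in Dux KO controls (0.12), ribosome genes in Dux KO under drug (0.064), the 2-cell list in the p53 KO response (0.060) and the p53 targets in the Dux KO interaction (0.23). Outside multigene families, 2-cell genes were then called in the Dux KO interaction (0.013). Block and recovered counts together gave 8329 in the p53 KO response, 13106 in the Dux KO response, 8715 and 3791 in the p53 KO and Dux KO interactions, and 3151 and 3016 in their controls, with 3191 rises shared by wild-type and p53 KO and 5250 rises and 5081 falls shared by wild-type and Dux KO. Recovered counts alone left 1099 falls shared by wild-type and p53 KO.

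Keeping the copied column, which puts a drug-treated library among the controls, gave 0 in the Dux KO response, 962 in the Dux KO interaction, 9 in Dux KO controls, 5043 in Dux KO under drug, 324 in the p53 KO response, 1573 in the p53 KO interaction and 4 in p53 KO controls.

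With an estimated correlation the adjusted p of p53 targets was 0.59 in the wild-type response, 0.49 in the Dux KO response, 0.56 in the p53 KO interaction and 0.25 in p53 KO controls, and that of 2-cell genes 0.37, 0.25, 0.65, 0.37 and 0.25 in the wild-type response, p53 KO interaction, Dux KO interaction, p53 KO controls and Dux KO under drug. Fry gave 0.059 for p53 targets in the p53 KO interaction, 0.33 for 2-cell genes in the Dux KO interaction and 0.075 in p53 KO controls.

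Without 1 library in turn, counts of calls ranged from 4291 to 5002 in the Dux KO response, 3077 to 6357 in the p53 KO interaction, 362 to 789 in the Dux KO interaction, 30 to 170 in p53 KO controls, 8184 to 12083 in p53 KO and 3731 to 5000 in Dux KO under drug, and stayed between 10397 and 11384 in the wild-type response. They were 0 in Dux KO controls. Exchanging Dux KO control 1 for the recovered control 2, which changes both choices at once, gave 8813 in the Dux KO response, 952 in the Dux KO interaction and 866 in Dux KO controls. In the p53 KO response the adjusted p ranged from 2.9e-25 to 0.27 for 2-cell genes and from 1.2e-05 to 0.37 for p53 targets. Log2 values there ranged from -3.66 to 0.27 for 6330410L21Rik, -0.12 to 3.29 for BC080695, -0.43 to 1.03 for Gm18363, -0.63 to 3.28 for Gm33248, -0.56 to 3.36 for Gm47631, -0.28 to 3.17 for Gm9343, -0.51 to 0.84 for Rln3, -0.40 to 0.79 for Trp53 and -1.67 to 0.98 for Ugt3a2. The fits also gave -4.96 to 5.25 for Gm11544 and -4.70 to 4.11 for Gm21033 there, and for Duxf3 -3.58 to 6.13 in p53 KO controls and -9.38 to 0.33 in the p53 KO interaction. The falls of Gm11544 and Gm21033 and both ends for Duxf3 rest on a group at 0 counts, so the fit's offset sets them and they show no change. Dab2 in the Dux KO response stood at 1.34 and 1.97 without 1 library and at -0.17 with control 1 exchanged for the recovered control.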

Other observations

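The X-linked genes and the chromosome-copy, long-gene and copied-column tests in this part were chosen after the results were seen. Those for GC content, length and depth came before. A group of X-linked genes was low in the lone Dux KO control, though all Dux KO control calls were lost without either wild-type control. Of the 99 lower calls, 10 lay on the X chromosome, against 3.7 expected (odds ratio 2.91), picked out after they were seen. They were the homeobox genes Rhox5, Rhox6 and Rhox9, the deubiquitinase gene Usp26, the cancer-testis genes Magea2 and Mageb4, and Gm773, Gm41, Gm371 and Map7d2. Rhox5 stood at 55.6 and 62.9 CPM in wild-type controls, 67.1 and 43 in p53 KO controls, 2.10 in Dux KO control 1 and 11.1 in control 2 as recovered. Magea2 stood at 11 and 11.6 CPM in wild-type, 0.431 and 1.67 in p53 KO and 0.210 in Dux KO control 1. After drug Rhox9 stood at 17.4 and 15.5 CPM in wild-type and 4.80 and 5.12 CPM in Dux KO cells.

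Whole chromosomes were shifted in line 1 of the p53 KO cells. In p53 KO control 1 the genes of chromosome 8 stood a median log2 of 0.43 above the wild-type mean, and 87.3% of them lay above the median of all genes against 47.9% of other genes. Bias from GC content or gene length does not account for it, since 0.40 was left after regression on GC, span, exonic length and level over 13615 genes. The difference of line 1 from line 2 was 0.56 on chromosome 8, 0.40 on chromosome 6 and -0.35 on chromosome 3 in controls, and 0.57, 0.41 and -0.39 in drug libraries, with r = 0.99 over 20 chromosomes (permutation p = 1e-05, the smallest possible with 100000 permutations). That is consistent with a gain of chromosome 8 in part or all of that line, for which 3 copies over 2 would give 0.58, but DNA was not measured here.

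Kept under its label, the copied count column left no gene called in the Dux KO response. A column holding another library would explain this: the SD of the log2 ratio of its counts to the FPKM of its own label was 0.834. An absent response in Dux KO cells would not, because 9531 genes were called with the recovered counts.

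Protein-coding genes spanning more than 200 kb (662 genes) had a median log2 of 0.67 in the wild-type response, -0.11 in the p53 KO response and -0.10 in the Dux KO response, and stood at 0.28 in the lone Dux KO control against wild-type controls. With every library thinned to a common depth, drug-treated wild-type libraries held counts for 5163 more genes than wild-type controls on average, p53 KO ones for 4100 more than theirs and Dux KO ones for 2797 more, with control 2 as recovered.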
